A study of Mus musculus with 3 samples.

How the data were processed

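The labels describe single-nucleus RNA sequencing of the mouse nucleus accumbens after stereotaxic delivery of an HSV vector, with 1 library for each of the constructs ZFP189WT, ZFP189VPR and ZFP189NFD. Per the labels, the mice received cocaine for 3 days, nuclei were prepared with myelin removal and a density gradient, and 3' gene expression libraries were made with droplet barcoding. Per the labels' protocols, each construct sequence was added to the mm39 genome with an exon entry beside the GENCODE vM32 annotation. Cell Ranger 7.1.0 and Seurat 4.3 are named in the submitters' processing notes. The design text of the series speaks of RNA-seq of tissue punches, and how the table with 1 value per gene and library was made is not stated. It may hold sums over nuclei or RNA of whole tissue. Which tool made it, which nuclei entered if any did, whether reads or unique molecular identifiers were summed, and how strand and reads with several matches were handled are not given in the sources used here.

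The deposited table holds log2 values, 1 column per library, which the authors made from counts by dividing by 1 factor per library, adding 1 and taking the logarithm, as read from the values themselves because neither the labels nor the file header state these steps. When the logarithm was undone, every value of every column was a whole multiple of that column's smallest step (100% of values within 0.01), and the multiples were taken as the counts. The factors implied by the steps were 0.959 for WT, 1 for NFD and 1.04 for VPR. A median-of-ratios calculation over the 31659 genes counted in all libraries gave the same factors, so the authors' scaling treats the median gene as equal between libraries. A difference that affects most genes alike is therefore not visible in these values.

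The table lists 54232 Ensembl mouse gene IDs, of which 16277 were 0 in all libraries. Symbols, gene types and coordinates came from GENCODE vM39 on GRCm39, the assembly that mm39 names, in a later annotation release than the authors used. It matched 50129 of the IDs. The 4103 unmatched IDs, which held 1.20% of counts in WT, 1.37% in NFD and 1.20% in VPR, stayed in the totals and in counts of genes by size. Each column was tied to its construct by its name. The column of the NFD construct is named with DN in place of NFD and carries the word RESUB, as does the description of that sample and of no other, and the labels do not explain the word.

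Total counts were 77631351 for WT, 83998166 for NFD and 87718978 for VPR. A gene with 0 counts in a library has a share of at most 3.86e-06% in WT, 3.57e-06% in NFD and 3.42e-06% in VPR, taking 3 counts as the limit. Intervals of a count are 95% exact Poisson intervals, shares carry exact Clopper-Pearson intervals, and fold differences carry exact intervals from the binomial split of the summed count of both libraries. They cover counting error only, and where reads rather than molecules were summed they are too narrow. Differences between animals, injections and preparations are in none of them.

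The comparisons were VPR against NFD, WT against NFD and VPR against WT. A moderated linear model had been planned for a table with replicates. With 1 library per construct no test was possible, and each gene was described by log2 of the ratio of normalized counts with a pseudocount of 1, over genes with a mean of at least 10 normalized counts in the libraries compared. The thresholds of 10 and 50 had been set for the deposited values before their log2 scale was known, and were applied to the normalized counts behind them. Genes differing by at least 2-fold were counted beside the number that counting error alone gives, as the mean of 20 simulated pairs of equal libraries.

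The 26 gene lists (14 of pathways and 12 of cell type markers) and the rule for named genes were fixed before the data were examined. The pathway lists cover immediate early genes, interferon response, antigen presentation, transposable element silencing, nucleic acid sensing, neuropeptides, dopamine signalling, glutamate receptors, GABA receptors, the opioid system, synaptic adhesion and scaffold, the mitochondrial genome, acute inflammation and injury, and stress and apoptosis. The marker lists cover D1, D2 and all medium spiny neurons, interneurons, glutamatergic neurons, astrocytes, oligodendrocytes and their precursors, microglia, vascular cells, ependymal and choroid plexus cells, and infiltrating immune cells. Some lists share members, so their medians are not independent. Dopamine signalling shares Drd1, Drd2, Ppp1r1b, Adcy5, Pde10a, Pde1b and Rgs9 with the lists of medium spiny neurons. Neuropeptides share Pdyn and Penk with the opioid system, and Sst, Npy, Vip and Cck with interneurons. A list's median was placed among 10000 random lists of the same size, drawn from 20 classes of mean expression, as a description of these libraries. Named genes are, per comparison, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 50, the 2 members of each list with the largest ratios in either direction, and Zfp189. Gene models known only by a clone or model number were passed over: 11 higher and 22 lower for VPR against NFD, 0 and 45 for WT against NFD, and 121 and 0 for VPR against WT. Some genes that the rule names are not reported here.

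Genes that overlap another gene are uncertain because strand handling is not known, as for Cxcl10 with Art3 and Ifit1 with Ifit1bl2, which lie on opposite strands. Near-identical relatives such as Hspa1a and Hspa1b, the H2 genes, granzymes, pseudogenes and small RNA genes are uncertain in the same way. Alternatives tried were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, median-of-ratios rescaling over genes with a mean of at least 50, and upper-quartile rescaling. Random lists of protein-coding genes, matched on mean expression or on mean expression and gene length, were added after the data were seen.

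The steps were tested on simulated data with counts drawn for the real genes. For VPR against NFD (26016 genes), 100 genes changed 1.5-fold (log2 0.58) came back at a median log2 of 0.59 and 100 changed 2-fold at 1.001, and 6 of 100 unchanged lists lay outside the central 95% of random lists. For WT against NFD (26031 genes) the medians were 0.58 and 0.997, with 6 of 100 unchanged lists outside. For VPR against WT (25972 genes) they were 0.58 and 1.003, with 1 of 100 outside. All simulated counts were recovered (100%). The unchanged lists were random genes in libraries that differ by counting error only. They check the steps and do not show how often lists of genes that vary together would lie outside in real libraries. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.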

Results

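RNA was measured in the mouse nucleus accumbens, a ventral part of the striatum that takes part in reward. The tissue came from mice given cocaine for 3 days, and it had received a herpes simplex virus (HSV) vector, a virus stripped down to carry a chosen gene into brain cells. Each vector carried 1 form of ZFP189, a zinc finger transcription factor, and the forms are labelled ZFP189WT, ZFP189VPR and ZFP189NFD. The labels do not spell out the abbreviations VPR and NFD. The labels describe single-nucleus RNA sequencing, which tags the RNA of each nucleus in a droplet before the libraries are read, while the design text of the series speaks of RNA-seq of tissue punches. The table used here holds 1 value per gene and library, so cell types were not separated, and whether its values come from nuclei or from whole tissue RNA is not settled by the sources used here. There was 1 library per construct, called here the WT, VPR and NFD library. Their totals were 77631351 counts for WT, 83998166 for NFD and 87718978 for VPR, over 34603, 34663 and 34740 genes with a count.

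With 1 library per construct, no difference below has a replicate check, and no p-value is given. A gene described as higher or lower was so in that library, and intervals cover counting error only. Fold differences are ratios of normalized counts with 95% exact intervals, and log2 ratios carry a pseudocount of 1. A gene list is described by the median log2 ratio of its members, set among the medians of 10000 random lists of equal size and matched mean expression. The series concerns transposable elements, mobile repeats in the genome, in medium spiny neurons, the projection neurons of the striatum, and their relation to cocaine. Transposable elements and the delivered constructs themselves were not analysed here, because the table lists mouse genes.

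Zfp189, the mouse gene of the delivered factor (ENSMUSG00000039634, chromosome 4, positions 49521176 to 49533793 on the plus strand of GRCm39), had similar counts in all 3 libraries. The WT library held 680 counts, or 709 normalized counts (95% exact Poisson interval 657 to 765). The NFD library held 625 counts, or 625 normalized counts (577 to 676), and the VPR library 679 counts, or 650.0 normalized counts (602 to 701). The log2 ratio was 0.18 for WT against NFD and 0.06 for VPR against NFD, and the latter was -0.01 under upper-quartile rescaling. Per the labels, each construct was added to the genome as a sequence of its own, and how reads that match both the construct and the gene were counted is not given in the sources used here. The level of Zfp189 is therefore no check on delivery.

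The first comparison set the VPR library against the NFD library. Genes of interferon signalling, antigen presentation, inflammation and blood vessels had higher counts in the VPR library. All 25 interferon response genes compared were higher, with a median log2 ratio of 0.64 that lay above all 10000 random lists. Cxcl10, an interferon-induced chemokine, was 3.00-fold higher (2.76 to 3.25, from 2411 against 770 counts), and Ifit1, an interferon-induced antiviral gene, was 2.49-fold higher (2.25 to 2.76). Among the lowest genes, Oxt, which encodes the precursor of oxytocin, was 8.99-fold lower in the VPR library (7.27 to 11.2, from 95 against 818 counts), and Sst, which encodes somatostatin, was 2.05-fold lower (2.001 to 2.09).

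Antigen presentation genes were higher in 11 of 12 cases in the VPR library (median log2 0.79, above all 10000 random lists). H2-D1, a classical major histocompatibility gene, was 2.53-fold higher (2.47 to 2.59), and Tap2, a subunit of the peptide transporter, was 2.64-fold higher (2.41 to 2.89). All 18 genes of acute inflammation and injury were higher (median log2 0.89, above all 10000 random lists). Ccl2, a chemokine that attracts monocytes, was 6.37-fold higher (5.13 to 7.99), and Lcn2, an acute-phase gene of reactive astrocytes, was 5.69-fold higher (3.96 to 8.39). Of 12 genes that sense nucleic acids in the cytosol and endosome, 8 were higher (median log2 0.22, above 9465 of 10000 random lists), led by Ifi204 at 2.12-fold (1.91 to 2.35). Another member, Tlr9, rested on 9 against 13 counts and was not separated from equality (1.51-fold lower, with an interval that included 1). Immediate early genes, which neurons switch on rapidly after stimulation, were higher in 15 of 18 cases (median log2 0.40, above 9998 of 10000 random lists), with Egr4 1.69-fold (1.51 to 1.89) and Egr2 1.65-fold higher (1.31 to 2.09).

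Markers of other cell types moved beside these groups. All 8 vascular markers were higher in the VPR library (median log2 1.14), led by Ly6c1 at 3.97-fold (3.58 to 4.42) and the endothelial junction gene Cldn5 at 3.69-fold (3.19 to 4.27). Ependymal and choroid plexus markers were higher in 4 of 5 cases (median log2 1.46), with Tmem212 4.10-fold (2.77 to 6.23) and Ccdc153 3.32-fold higher (1.91 to 6.08). Infiltrating immune markers were higher in 8 of 9 cases (median log2 0.76), with Gzmb, a protease of cytotoxic lymphocytes, 3.20-fold (2.90 to 3.53) and Ly6c2 2.63-fold higher (2.48 to 2.79). Astrocyte markers were higher in 7 of 8 cases (median log2 0.38), with Gfap at 2.16-fold and Aqp4 at 1.67-fold, and oligodendrocyte markers in 8 of 8 (median log2 0.42), with Ermn at 2.19-fold. Each of these 5 medians lay above at least 9996 of 10000 random lists. Microglial markers (median log2 0.13) and oligodendrocyte precursor markers (0.01, and -0.06 under upper-quartile rescaling) lay within the central 95% of random lists. Tmem119 was 1.28-fold lower among the former, and Pdgfra was 1.31-fold higher and Gpr17 1.25-fold lower among the latter.

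Neuronal groups had smaller ratios, most of them lower in the VPR library. Dopamine signalling genes were lower in 10 of 13 cases (median log2 -0.21, below 9944 of 10000 random lists), with the receptor gene Drd1 1.53-fold lower (1.48 to 1.58), while Slc6a3 rested on 8 against 13 counts. Opioid system genes were lower in 6 of 8 cases (median log2 -0.22, below 9915 of 10000 random lists), with the nociceptin receptor gene Oprl1 1.63-fold lower (1.49 to 1.79) and the mu receptor gene Oprm1 1.31-fold higher (1.27 to 1.35). Medians of neuropeptides (-0.17), GABA receptors (-0.16), glutamate receptors (-0.14), synaptic adhesion and scaffold genes (-0.11), interneuron markers (-0.08) and glutamatergic neuron markers (-0.08) lay within the central 95% of random lists, though the neuropeptide median stood at percentile 0.53 of lists also matched on gene length. Within those lists Npy, which encodes neuropeptide Y, was 1.65-fold lower (1.60 to 1.70), Gabrb2 1.28-fold, Nlgn1 1.21-fold, Cntn4 1.18-fold and Slc30a3 1.99-fold lower, and Grm2 was 1.32-fold and Neurod6 2.03-fold higher. Markers of medium spiny neurons were close to equal, at a median log2 of -0.10 for the D1 type, 0.04 for the D2 type and -0.03 for both types. Chrm4 was 1.61-fold, Drd2 1.26-fold, Rgs9 1.30-fold and Adcy5 1.26-fold lower there, and Penk 1.19-fold higher.

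Transposable element silencing genes showed no common direction, with 12 of 23 higher in the VPR library (median log2 0.02, and -0.05 under upper-quartile rescaling). The largest ratios there were those of Mphosph8, a subunit of the HUSH silencing complex, at 1.43-fold higher (1.38 to 1.48), and of Daxx, a histone H3.3 chaperone, at 1.24-fold higher (1.10 to 1.39). Stress and apoptosis genes were higher in 9 of 14 cases (median log2 0.09), with Hspa1b 1.61-fold higher and Chac1 1.59-fold lower. All genes on the mitochondrial chromosome, including transfer RNA genes outside the fixed list, took 0.540% of counts in the VPR library (95% Clopper-Pearson interval 0.538% to 0.541%). In the NFD library they took 0.400% (0.398% to 0.401%). The 13 genes of the fixed list did not move together: mt-Nd3 was 8.89-fold higher (8.26 to 9.57) and mt-Atp8 2.56-fold higher (2.35 to 2.78), but 3 of the 13 genes were lower (median log2 0.28, above 9998 of 10000 random lists and above 83.4% of lists also matched on gene length). One of the lower genes, mt-Atp6 (log2 -0.64), overlaps mt-Atp8 on the same strand, so the split of counts between them is uncertain. Shorter nuclear protein-coding genes were higher, from a median log2 of 0.14 in the shortest of 10 length classes to -0.11 in the longest (rank correlation -0.24 across 14855 genes).

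By size alone, 968 genes were at least 2-fold higher and 444 at least 2-fold lower in the VPR library, of 26016 genes with a mean of at least 10 normalized counts. Counting error alone gave 86.6 and 76.6 genes on average in simulated equal libraries. Upper-quartile rescaling gave 821 higher and 563 lower, which is 59.3% higher against 68.6% with the deposited scaling. The balance depended on low counts: with no filter 2313 were higher and 3302 lower (41.2% higher), where counting error alone gave 1105 and 2083, and with a mean of at least 50 these were 483 and 142. The 12 highest genes also held Mir5136, Snord35a, H2ac24, Gzmc, Mrpl27-ps, Or14j4, Mir6236, Klf2 and Tmem252, and the 12 lowest held R3hdml, Cyp2d36-ps, Igfn1, Bc1, Mir684-1, n-R5s25, Uba52rt, Scart1, Gemin4, BC051077 and Iglc1. Klf2, a transcription factor of endothelial cells and lymphocytes, was 4.83-fold higher (3.86 to 6.09), and Bc1, a short noncoding RNA of neurons (chromosome 7, positions 144468199 to 144468374), was 4.89-fold lower (4.69 to 5.10, from 2644 against 12382 counts). Most of the other names lie inside or across another gene or belong to families of near copies, such as Snord35a within Rpl13a, so their values are uncertain, as is the split between the close relatives Ly6c1 and Ly6c2 or among the H2 genes. Klf2 and Bc1 overlap gene models on the other strand.

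**Figure D1:**
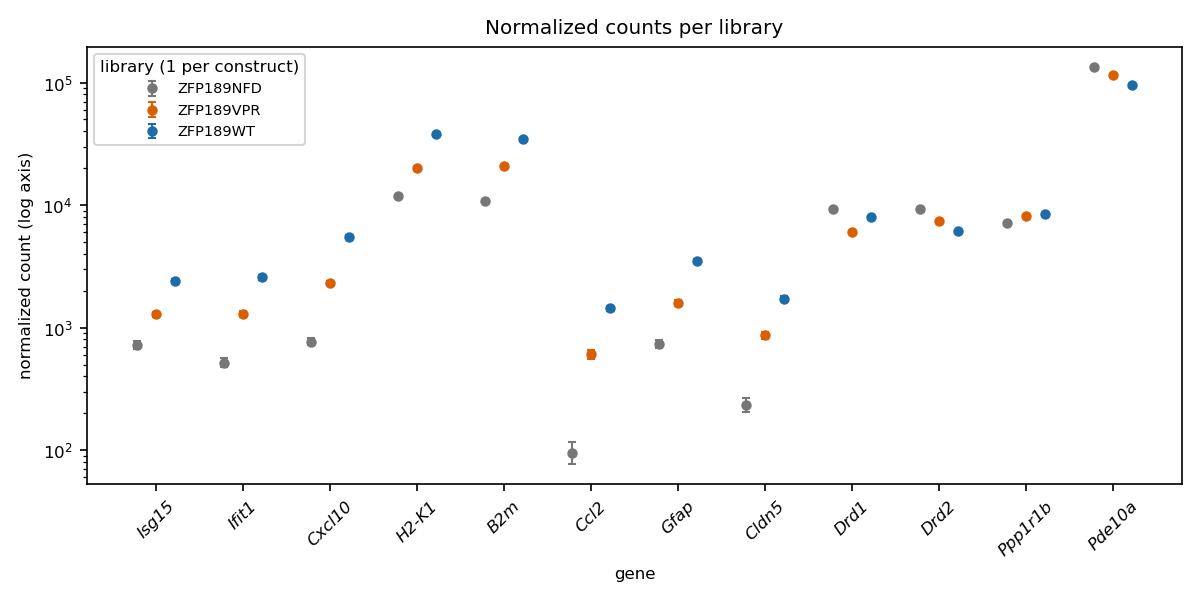
Normalized counts (vertical axis, log scale) of 12 genes from the fixed lists, chosen for the plot after their values were seen, in the NFD, VPR and WT libraries. Points are single libraries and bars are 95% exact Poisson intervals, often smaller than the point; the interferon gene Cxcl10 lay at 770 in NFD, 2308 in VPR and 5532 in WT.

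The second comparison set the WT library against the NFD library. Interferon, antigen presentation and inflammation genes again had higher counts, with larger median ratios than in the VPR library: 25 of 25 interferon response genes, 12 of 12 antigen presentation genes and 18 of 18 inflammation and injury genes were higher in the WT library, at median log2 ratios of 1.36, 1.60 and 1.69, each above all 10000 random lists. Cxcl10 (chromosome 5, positions 92494497 to 92496748) was 7.18-fold higher (6.66 to 7.76, from 5303 against 770 counts), and Ccl2 (chromosome 11, positions 81926397 to 81928279) was 15.1-fold higher (12.2 to 18.8, from 1374 against 95 counts). Genes of the mitochondrial genome were higher in 13 of 13 cases (median log2 1.29), and mt-Nd3, a subunit of respiratory complex I, was 27.2-fold higher (25.4 to 29.3). Oxt was 3.77-fold lower in the WT library (3.23 to 4.41), and Sst was 1.74-fold lower (1.71 to 1.78).

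Within those groups, Ifit1 was 4.97-fold (4.52 to 5.47), Tap2 4.74-fold (4.36 to 5.17), H2-D1 4.20-fold (4.11 to 4.303) and Lcn2 11.5-fold higher (8.13 to 16.8). Nucleic acid sensing genes were higher in 10 of 12 cases (median log2 0.54, above 9993 of 10000 random lists), with Ifi204 2.71-fold and Tlr3, a receptor for double-stranded RNA, 1.92-fold higher (1.72 to 2.15). Immediate early genes were higher in 15 of 18 cases (median log2 0.43, above 9998 of 10000 random lists), with Junb 1.79-fold (1.69 to 1.90) and Ier2 1.64-fold higher (1.35 to 2.001). Stress and apoptosis genes were higher in 12 of 14 cases (median log2 0.34, above 9867 of 10000 random lists, and above 74.4% of lists also matched on gene length), with the heat shock genes Hspa1b at 2.90-fold (2.01 to 4.25) and Hspa1a at 2.02-fold (1.52 to 2.69).

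Markers of glial, vascular and immune cells were higher beside these groups. Vascular markers were higher in 8 of 8 cases (median log2 1.79), with Cldn5 at 7.35-fold (6.40 to 8.46) and the pericyte gene Rgs5 at 5.22-fold (4.55 to 6.01). Ependymal and choroid plexus markers were higher in 5 of 5 cases (median log2 2.19), with Ttr, which encodes transthyretin, at 9.24-fold (4.23 to 23.9) and Tmem212 at 7.34-fold (5.05 to 10.98). Infiltrating immune markers were higher in 9 of 9 cases (median log2 1.06), with Gzmb at 4.27-fold (3.88 to 4.70) and Ly6c2 at 4.18-fold (3.94 to 4.42). Astrocyte markers were higher in 7 of 8 cases (median log2 0.92), with Gfap at 4.77-fold (4.40 to 5.17) and Aqp4 at 2.93-fold (2.73 to 3.14), and microglial markers in 8 of 9 (median log2 0.74), with Aif1 at 2.28-fold (2.04 to 2.55) and C1qa at 2.11-fold (2.05 to 2.17). Oligodendrocyte markers were higher in 8 of 8 cases (median log2 0.62), with Ermn at 1.88-fold, and precursor markers in 5 of 6 (median log2 0.45), with Pdgfra at 1.61-fold and Olig2 at 1.43-fold. These 7 medians lay above at least 9816 of 10000 random lists, and that of the precursors lay above 96.7% of lists also matched on gene length.

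Among neuronal groups, markers shared by both types of medium spiny neurons were lower in 10 of 13 cases in the WT library (median log2 -0.23, within the central 95% of random lists), while those of the D1 and D2 types went both ways. The shared markers had Rgs9, a regulator of dopamine receptor signalling, 1.60-fold (1.57 to 1.63) and Pde10a, a phosphodiesterase of these neurons, 1.39-fold lower (1.38 to 1.40). Dopamine signalling genes were lower in 10 of 13 cases (median log2 -0.28, below 9968 of 10000 random lists). Drd2 was 1.53-fold (1.48 to 1.58), Drd1 1.15-fold (1.12 to 1.19) and Chrm4 1.40-fold lower, and Gpr6 1.25-fold higher, while D1 markers were higher in 5 of 9 cases (median log2 0.07, and -0.04 under upper-quartile rescaling) and D2 markers in 4 of 7 (0.11). Glutamate receptor genes were lower in 14 of 15 cases (median log2 -0.22), with Grm2 1.72-fold higher. GABA receptor genes were lower in 10 of 13 (median -0.14), with Gabrb2 1.25-fold lower and Gabrd 1.34-fold higher, and synaptic adhesion and scaffold genes in 13 of 17 (median -0.15), with Nlgn1 1.30-fold and Cntn4 1.27-fold lower. Medians were -0.01 for opioid genes, 0.12 for neuropeptides, 0.05 for interneuron markers (-0.06 under upper-quartile rescaling) and 0.39 for glutamatergic neuron markers. In those lists Oprd1 was 1.31-fold, Oprl1 1.14-fold and Chat 1.57-fold lower, and Cck 1.52-fold and Neurod6 2.35-fold higher. Apart from dopamine signalling, these lists lay within the central 95% of random lists. Many dopamine signalling genes, Rgs9, Pde10a, Drd1 and Drd2 among them, are also medium spiny neuron markers, so that list is not a separate result.

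Transposable element silencing genes were higher in 15 of 23 cases in the WT library, with a median log2 of 0.05 that was -0.06 under upper-quartile rescaling. Uhrf1, which guides maintenance of DNA methylation, was 1.55-fold higher (1.10 to 2.20, from 86 against 58 counts), and Daxx 1.37-fold higher (1.22 to 1.54). All genes on the mitochondrial chromosome, not only the fixed list, took 1.57% of counts in the WT library (95% Clopper-Pearson interval 1.56% to 1.57%). The gene mt-Atp8 was 6.17-fold higher than in the NFD library (5.71 to 6.67). It overlaps mt-Atp6 (log2 0.81) on the same strand, so the split of counts between them is uncertain. Another 6 mitochondrial names, the transfer RNA genes mt-Tk, mt-Te, mt-Tr, mt-Tp, mt-Ts2 and mt-Tg, stood among the 12 highest genes at 12.7-fold to 22.1-fold. Shorter genes were higher: the median log2 ratio was 0.31 in the shortest of 10 length classes of nuclear protein-coding genes and -0.19 in the longest, and the rank correlation with length across 14948 genes was -0.39, where genes are not independent replicates.

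By size alone, 1582 genes were at least 2-fold higher and 569 at least 2-fold lower in the WT library, of 26005 compared, where counting error alone gave 82.6 and 95.2. Upper-quartile rescaling, which took the median of genes with a mean of at least 50 from -0.01 to -0.12, gave 1261 and 751, which is 62.7% higher against 73.5%. With no filter on low values the counts were 4593 and 3428, where counting error alone gave 2124 and 2017, and with a mean of at least 50 they were 994 and 160. Sox18, a transcription factor of endothelial cells, led the 12 highest genes at 36.3-fold (13.8 to 135, from 139 against 4 counts), and these also held Rpl39-ps1, Mir5136 and H2ac24. The 12 lowest held Cyp2d36-ps, R3hdml, Mir684-1, Bc1, Tpi-rs9, n-R5s25, Scart1, Hmgn2-ps, Gemin4, Bnc2 and Mir1193 beside Oxt. Bc1 was 3.56-fold lower (3.42 to 3.70), and Bnc2, a zinc finger gene, 2.86-fold lower (2.38 to 3.45).

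Because both comparisons use the NFD library, their ratios share its chance values. Across 20832 genes with a mean of at least 50, the ratios of VPR and WT against NFD had a correlation of 0.76 and a covariance of 0.154, against 0.50 and 0.00681 in simulated equal libraries. Of these genes, 371 were at least 2-fold higher in both comparisons and 79 at least 2-fold lower in both, where independent lists of the same sizes would share 24.99 and 0.924. Part or all of that excess may come from the shared library, which is a single one and cannot be split.

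**Figure D2:**
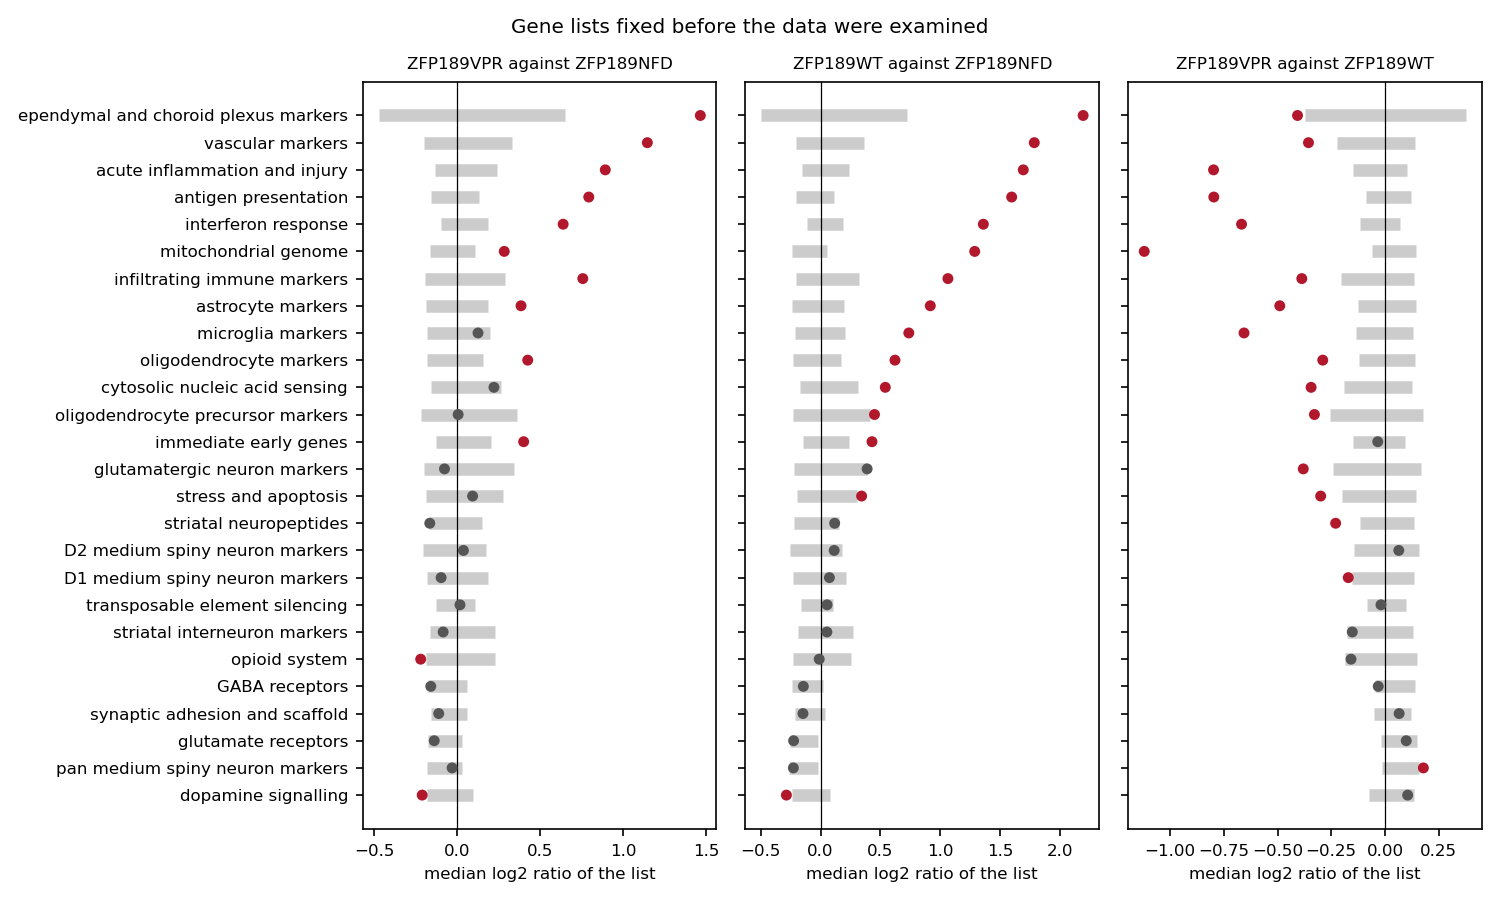
Median log2 ratio (horizontal axis) of the 26 fixed gene lists in the 3 comparisons; grey bars span the central 95% of 10000 random lists matched on mean expression, and red points lie outside them. Interferon response genes lay at 0.64 for VPR against NFD, 1.36 for WT against NFD and -0.67 for VPR against WT.

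**Figure D3:**
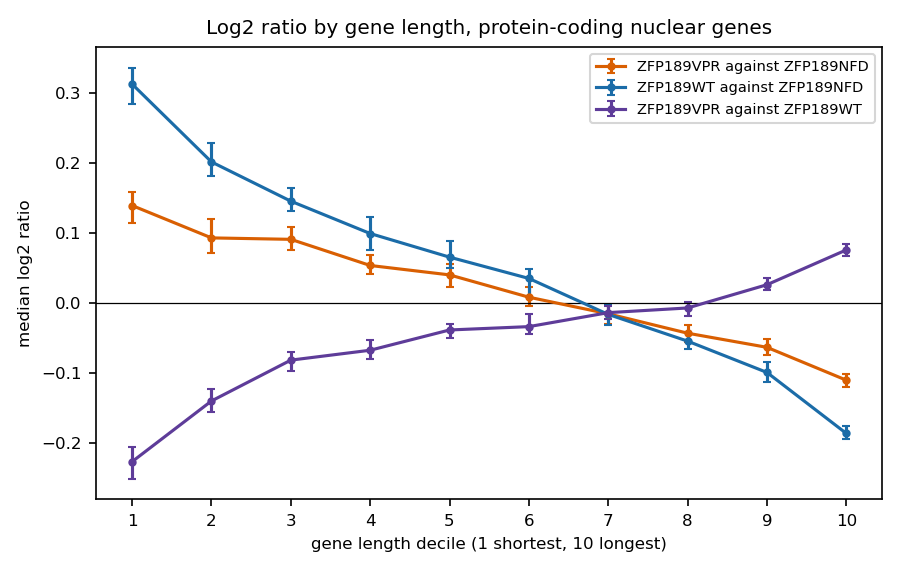
Median log2 ratio (vertical axis) of nuclear protein-coding genes in 10 classes of gene length from shortest to longest (horizontal axis), with 95% bootstrap intervals over genes. The WT against NFD line runs from 0.31 in the shortest class to -0.19 in the longest, the VPR against NFD line from 0.14 to -0.11, and the VPR against WT line from -0.23 to 0.08.

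The third comparison set the VPR library against the WT library. Interferon, antigen presentation, inflammation and mitochondrial genes had lower counts in the VPR library. All 25 interferon response genes (median log2 -0.67), 12 antigen presentation genes (-0.80), 18 inflammation and injury genes (-0.80) and 13 genes of the mitochondrial genome (-1.12) were lower, each median below all 10000 random lists. Cxcl10 was 2.40-fold lower (2.28 to 2.52), Bst2, an interferon-induced antiviral membrane protein, 2.18-fold lower (2.09 to 2.28), and mt-Nd3 3.06-fold lower (2.98 to 3.15). Drd1 was 1.33-fold lower (1.28 to 1.37) and Drd2 1.22-fold higher (1.17 to 1.26) in the VPR library.

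Tap1 was 1.96-fold and Tapbp 1.98-fold lower, both parts of the peptide loading machinery, and Ccl2 2.37-fold and Serpina3n 2.36-fold lower. Nucleic acid sensing genes were lower in 11 of 12 cases (median log2 -0.34, below 9991 of 10000 random lists), with Tlr3 1.68-fold (1.51 to 1.87) and Sting1 1.57-fold lower (1.39 to 1.79). Astrocyte markers (median log2 -0.49), microglial markers (-0.66), infiltrating immune markers (-0.39), vascular markers (-0.36), oligodendrocyte markers (-0.29), their precursors (-0.33) and ependymal markers (-0.41) had medians below 0 and outside the central 95% of random lists. Gfap was 2.20-fold, Aldoc 1.85-fold, Aif1 2.09-fold, C1qa 1.77-fold, Cldn5 1.99-fold, Vtn 1.84-fold, Ly6c2 1.59-fold, Mobp 1.28-fold, Gpr17 1.73-fold, Olig1 1.33-fold, Tmem212 1.79-fold and Ttr 3.07-fold lower. Ms4a1, on 24 against 37 counts, was not separated from equality (1.68-fold lower, 0.979 to 2.94). Stress and apoptosis genes were lower in 13 of 14 cases (median log2 -0.30), with Hspa1b 1.80-fold and Gadd45a 1.61-fold lower. The lists of ependymal markers and of stress genes lay within the central 95% once random lists were also matched on gene length.

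Markers of medium spiny neurons of both types were higher in 10 of 13 cases in the VPR library (median log2 0.18, above 9934 of 10000 random lists). Rarb, a retinoic acid receptor gene, was 1.37-fold higher (1.36 to 1.39). D1 markers were lower in 6 of 9 cases (median log2 -0.17) with Pdyn, the dynorphin precursor gene, 1.41-fold lower (1.36 to 1.47), and D2 markers were near 0 (0.06) with Gpr6 1.22-fold lower. Neuropeptide genes were lower in 9 of 11 cases (median log2 -0.23, below 9985 of 10000 random lists), with Tac2 1.52-fold lower (1.41 to 1.64), and glutamatergic neuron markers in 8 of 8 (median log2 -0.38, below 9988), with Slc30a3 1.92-fold and Slc17a6 1.76-fold lower. The D1 and neuropeptide lists lay within the central 95% of lists also matched on gene length. Interneuron markers were lower in 10 of 12 cases (median log2 -0.15), with the parvalbumin gene Pvalb 2.02-fold lower (1.69 to 2.43). Dopamine signalling (median log2 0.11, but -0.04 with no filter on low values), glutamate receptors (0.10), GABA receptors (-0.03, and 0.02 under upper-quartile rescaling), opioid genes (-0.16) and synaptic adhesion genes (0.07) lay within the central 95% of random lists, as did the interneuron list. Among lists also matched on gene length, GABA receptors stood at percentile 0.825 and dopamine signalling at percentile 97.8, both outside the central 95%. Within them Th was 1.35-fold, Grm2 1.30-fold, Gabbr1 1.21-fold, Oprl1 1.43-fold, Nlgn3 1.35-fold and Lrrtm2 1.22-fold lower, and Gria1 1.19-fold higher.

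Immediate early genes (median log2 -0.03, and 0.01 under upper-quartile rescaling) and transposable element silencing genes (-0.02, and 0.03 under that rescaling) showed no common direction. Bdnf, a neurotrophin gene, was 1.47-fold lower (1.27 to 1.69) and Egr2 1.39-fold higher (1.11 to 1.73), and Trim28, the corepressor recruited by many zinc finger proteins, was 1.31-fold lower (1.21 to 1.42) while Uhrf1 was not separated from equality (1.36-fold lower, 0.978 to 1.89). By size alone, 398 genes were at least 2-fold higher and 357 at least 2-fold lower in the VPR library, of 25987 compared, where counting error alone gave 90.2 and 78.5. Upper-quartile rescaling gave 461 and 292, or 61.2% higher against 52.7%. With no filter on low values the balance turned to 1742 higher and 3005 lower, where counting error alone gave 1196 and 2009, with a mean of at least 50 the counts were 132 and 135, and with a pseudocount of 5 they were 242 and 234. Of the 12 lowest genes, 11 were mitochondrial transfer RNAs at 5.58-fold to 14.7-fold lower, and the other was Abhd12b at 6.20-fold (3.62 to 11.3). The 12 highest were Mir1970, Hsd3b5, Or13a25, Lexis1, Rpl15-ps4, Usp46os2, Ppp2r2cos, Gins2, Prss52, Adam28, Rpl19-ps12 and Or6c220-ps1, at up to 2.77-fold. Of these, 10 overlap another gene model, among them Gins2, a DNA replication factor gene whose span crosses Gse1 on the other strand, and none is a gene of a fixed list.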

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

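The random lists of protein-coding genes were chosen after seeing the data, and all other alternatives were fixed before. No named gene reversed where its interval excluded equality, and no list median reversed where the list lay outside the central 95% of random lists. Upper-quartile rescaling moved 52 of 217 named-gene values and 8 of 78 list medians beyond their intervals, and the other 5 settings moved 0. The changed filters could not move a named gene, because they only decide which genes enter. Median-of-ratios rescaling nearly repeated the deposited scaling, with factors of 0.9997 for WT, 0.9993 for NFD and 1.001 for VPR. For named genes, the 0 of these settings is therefore no sign of stability. Counts of genes differing by at least 2-fold depended on the treatment of low counts. The filters let fewer or more genes enter, while a pseudocount of 5 kept the same genes and made ratios of low counts smaller. With no filter, VPR against NFD gave 5615 genes (2313 higher, 3302 lower), WT against NFD 8021 (4593 and 3428) and VPR against WT 4747 (1742 and 3005), where counting error alone gave 1105 and 2083, 2124 and 2017, and 1196 and 2009. With a mean of at least 50 they gave 625 (483 and 142), 1154 (994 and 160) and 267 (132 and 135). A pseudocount of 5 left 294 lower genes for VPR against NFD, 374 for WT against NFD, and 476 (242 and 234) for VPR against WT. Lists outside the central 95% of random lists numbered 12, 15 and 17 of 26 in that order of comparisons, and 12, 13 and 15 when random lists were matched on gene length. No paired analysis was possible because each construct has 1 library. For the same reason, leaving out a library and a count model were not run. Genes with few counts, such as Tlr9 and Slc6a3, are limited by depth, and no setting bears on differences between animals.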

Other observations

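The tests of explanations in this part, and the lists of ribosomal protein genes, tissue-restricted families and Y-linked genes, were all chosen after the results were seen. Ribosomal protein genes, which encode the protein parts of the ribosome, were higher in 86 of 97 cases in the WT library than in the NFD library (median log2 0.77), in 70 of 97 in the VPR library (0.18), and lower in 89 of 97 in VPR against WT (-0.63). Rpl13 held 16351 normalized counts in WT, 9766 in VPR and 6977 in NFD. The nuclear noncoding RNA Malat1 took 8.38% of counts in the VPR library, 6.75% in WT and 5.38% in NFD, and Meg3, another nuclear noncoding RNA, took 0.735%, 0.699% and 0.816%. Neat1, the scaffold of nuclear paraspeckles, held 9359 normalized counts in WT, 8431 in VPR and 6606 in NFD. Avp, which encodes vasopressin and is made in the hypothalamus with Oxt, held 248 normalized counts in WT, 193 in VPR and 176 in NFD, so it was not low where Oxt was.

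All 3 libraries held counts of both Xist, the RNA of the inactive X chromosome, and Y-linked genes. Xist held 45055 normalized counts in WT, 51933 in NFD and 38418 in VPR. Uty held 6638, 6199 and 5533 in that order, Ddx3y 2846, 2224 and 2106, Kdm5d 3333, 3154 and 2842, and Eif2s3y 7862, 5932 and 5302. Among longer noncoding genes with a mean of at least 50, the median log2 ratio was 0.06 for VPR against NFD, -0.10 for WT against NFD and 0.12 for VPR against WT.

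Interferon, antigen presentation, inflammation and vascular genes (63 in all) were higher in the WT and VPR libraries than in the NFD library, at median log2 ratios of 1.51 and 0.73, with 63 and 62 of them higher. These lists were pooled after the values were seen, because their medians were among the highest. Part of each excess given below may follow from that choice. The intervals over genes do not cover it, and they treat genes that vary together as independent. Gene length is not the whole cause, since both medians lay above 100% of random protein-coding lists matched on length and expression. The medians exceeded those of ribosomal protein genes by 0.74 (95% interval over genes 0.55 to 0.93) for WT and 0.55 (0.45 to 0.77) for VPR. Apart from the choice of lists, an equal rise of all cytoplasmic RNA would not give this excess. Mitochondrial genes, though, had medians of 1.29 for WT and 0.28 for VPR. Such RNAs did not rise alike, and more cytoplasmic RNA stays open. A lower share of neurons, with the mix of other cells kept, would raise markers of those cells alike. The medians exceeded that of 30 glial markers by 0.89 (0.68 to 1.13) for WT and 0.52 (0.40 to 0.73) for VPR. Ependymal and choroid plexus markers, outside that comparison, had medians of 2.19 for WT and 1.46 for VPR. Vascular markers are themselves among the 63 genes. The comparison, made with lists picked for high medians, therefore speaks at most against an equal rise of all other cells. A changed mix of cells stays open. Stronger immune activation or more vascular and immune cells in the WT and VPR tissue are hypotheses that remain open, and the values do not tell an effect of the constructs from one of injection, animal or preparation. The NFD library, the only one with RESUB in its description, is in both differences, so its own handling may account for part of them and was not tested.

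Short genes, ribosomal protein genes and mitochondrial genes were higher in the WT library than in the NFD library. GC content does not account for the length trend, since the rank correlation with gene length across 14948 genes was -0.39 before and -0.39 after GC content was held fixed (-0.41 to -0.38), and the trend was weaker for VPR against NFD (-0.24) and reversed for VPR against WT (0.33), so it is not in the WT library alone. A candidate explanation is more cytoplasmic RNA in the WT library: ribosomal protein genes lay above 100% of protein-coding lists matched on length and expression, and the share of all genes on the mitochondrial chromosome was 1.57% in WT against 0.400% in NFD. Both values belong to the pattern to be explained, so they are no test of that explanation. Other values go against it as the whole cause, since the nuclear RNAs Malat1 (6.75% against 5.38% of counts) and Neat1 (9359 against 6606 normalized counts) were also higher in WT, though Meg3 was lower (0.699% against 0.816%), and log2 ratios of single mitochondrial genes ran from 0.55 for mt-Co2 to 4.77 for mt-Nd3. It stays open, as does an effect of the constructs, which was not tested, and what these levels mean depends on whether the values come from nuclei or whole tissue, which the sources do not settle.

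Processed pseudogenes, inserted copies of messenger RNAs, were higher in the VPR library than in the WT library in 341 of 502 cases with a mean of at least 50 (median log2 0.25), and than in NFD in 331 of 509 (0.26), while WT against NFD was near equal (223 of 466 higher, -0.04). The 2-fold calls for VPR against WT, higher and lower, were 49 and 4 among long noncoding genes and 46 and 3 among processed pseudogenes. They were 16 and 2 among gene models awaiting experimental support and 5 and 97 among protein-coding genes. Against NFD, the gene models awaiting support were not higher in VPR (576 of 1494 higher, median log2 -0.14). Their 2-fold calls there were 29 and 28, so not all such loci were higher in VPR against both libraries. Reads shared with parent genes stay open as a contribution, since in the wider set of 1159 pseudogenes with a mean of at least 10 a parent could be named for 105 only, and these were not higher as a group (median log2 -0.12) but exceeded their parents by a median of 0.33 (95% interval over parents 0.20 to 0.44, 79 of 105 above). Of the 105, 71 were named for ribosomal proteins, with parents at a median of -0.65. The other 34 had a median of -0.04 and exceeded their parents by 0.20 (0.003 to 0.33). In the wider set, the 73 pseudogenes named for ribosomal proteins had a median of -0.18 and the other 1086 one of 0.24. The 105 therefore do not stand for the wider set. More reads from otherwise silent loci in VPR may contribute: genes of tissue-restricted families, such as olfactory receptors, were higher in 68 of 106 cases in VPR against WT (median log2 0.17, above 100% of matched lists). These 106 passed the filter on low values, of 1830 such genes in all, so most of these loci were not compared. Against NFD, these families had a median of 0.18 in VPR, above 91.2% of lists, or above 79.85% of lists also matched on gene length. In WT their median was -0.15 (43 higher, 61 lower), below all lists, so the difference of these families, unlike that of the pseudogenes, rests in part on low values in WT. Genomic DNA in the preparations, in amounts that differ between libraries, and effects of either construct on silent loci are hypotheses that remain open and were not told apart here.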
